A study of Escherichia coli with 24 samples.

How the data were processed

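RNA of 4 Escherichia coli strains grown in a glucose-limited chemostat, in batch culture, or starved for 4 h after chemostat growth was sequenced in 24 libraries, 2 per strain and condition. Per the labels, RNA was extracted with a RiboPure kit, treated with DNase, enriched for mRNA with RiboMinus and sequenced on an Illumina HiSeq for 50 cycles, with 8 barcoded samples per lane. Which library ran on which lane is not given in the sources used here, so lane could not enter the model. The deposited count table holds raw read counts, which the authors made by mapping reads with Bowtie and counting them per pan-genome gene. The version of Bowtie, the counting program and any read filters are not given in the sources used here. The deposited normalized table holds signal values, which per the labels the authors made with DESeq, version not given. Tested on the files, all 150984 of its values equal the raw count times one factor per library to within 0.01 reads, with factors from 0.304 to 10.7. The deposited map gives the coordinates of a pan-genome gene in each strain in which it is mapped, and the annotation table gives product texts. No reference genome was used here, and no reads were mapped again.

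The count table has 6291 genes and the map 18394. The 3215 genes with coordinates in all 4 strains, called core genes, were analysed together. The strains have 4282 (MG1655), 4312 (IAI1), 4158 (TW11588) and 4569 (TW09308) mapped genes, and those not shared by all 4 were analysed only within strains. No gene of the count table is named as rRNA or tRNA, and 579 have no product text. Gene symbols were given to 1812 core genes. For 1112 of them, a gene name or locus tag in the TW11588 annotation matched the RefSeq gene table, with a coding length within 10%, and equal for all but 6. For 415, the product text held a protein name with equal coding length, and for 285 list members it named the known product with equal coding length. The rules for naming were set after the files were opened. tuf was left out because it has near-identical copies.

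Total counts per library run from 605126 in MG1655 starvation to 16143697 in MG1655 batch, and the report gives all 24. Replicate pairs varied 3.65 to 39.4 times as much as counting alone would make them (chi-square per degree of freedom). The pair of MG1655 starvation differed with an SD of 0.606 on the log2 scale.

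The groups, comparisons, tests, gene lists, threshold, rule for naming genes and first set of alternatives were chosen before the data were examined. edgeR 4.0.16 was run in R 4.3.3, with limma 3.58.1 for gene lists. Genes were kept by filterByExpr over the 12 groups, which left 3198, and libraries were scaled by TMM. One quasi-likelihood model of 12 group means was fitted to all 24 libraries with 12 residual degrees of freedom, a common dispersion of 0.00725 and 8.47 prior degrees of freedom. Contrasts were batch minus chemostat and starvation minus chemostat, for the mean of 4 strains and for each strain. Others were IAI1, TW11588 and TW09308 minus MG1655 in chemostat, and the mean of TW11588 and TW09308 minus that of MG1655 and IAI1. An F test asked whether the 4 strains had the same response. P-values were adjusted by Benjamini-Hochberg over the genes tested at a threshold of 0.05. Errors on log2 fold changes are standard errors, the size of the change over the square root of F. Levels are cpm from edgeR with TMM scaling, given as mean ± SD of 2 libraries. Where a group had 0 reads, folds were to be read against a floor of 3 reads.

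A total of 630 genes in 25 lists was fixed, of which 555 were matched to core genes and 7 to genes outside the core. The lists were ribosomal proteins, translation factors, RpoS-dependent general stress, acid resistance, ribosome hibernation, flagella and chemotaxis, glycolysis, high-affinity sugar uptake, acetate and fatty acid use, alternative carbon source use, TCA cycle, gluconeogenesis, aerobic respiration and ATP synthase, anaerobic metabolism, amino acid, pyrimidine and purine biosynthesis, nitrogen, phosphate and iron limitation or uptake, heat shock and chaperones, oxidative stress, SOS response, curli, cellulose and fimbriae, and colanic acid capsule. The 24 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, and all list p-values are Benjamini-Hochberg adjusted over lists and contrasts. Genes named by rank needed a symbol in the deposited annotation, other than one starting with y unless in a list, so genes not named can have larger changes or smaller p. For the mean of 4 strains they were the 10 largest rises and 10 largest falls past the threshold with one sign in all strains and a mean log2 cpm of at least 3, and the 4 members of each list with the smallest p. For differences in response they were the 8 genes with the smallest p. For strain contrasts they were the 5 largest in each direction, with 4 members of each list that passed.

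Alternatives were median-ratio size factors, DESeq2 1.42.0 (Wald and likelihood ratio tests), no filter beyond 1 read, at least 10 reads in every group, a replicate block over all strains or within strains, a 2-fold minimum, each of the 24 libraries left out in turn, and limma with trend on the deposited signal values with a pseudocount of 1. Strain differences were also fitted with coding length as an offset, in the other conditions and over all conditions, and each strain was fitted alone with its own genes. Lists were also tested with an estimated correlation and with fry. Added after the data were seen were leaving out the MG1655 starvation group, thinning all libraries to 605126 reads, and a replicate block with the TW09308 chemostat numbers crossed.

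The pipeline was tested on simulated counts with these group sizes and depths and 200 changed genes, each in a random direction. Far more genes were called in the data, 2567 of 3198 in batch in the mean of 4 strains. The rates that follow, and the scaling, were not tested at such a share of changed genes. edgeR found 94.0% of 1.5-fold and all of 2-fold and 4-fold changes in the mean of 4 strains, with 2.00% false among its calls. In MG1655 batch it found 77.6%, 100% and 98.5%, with 6.12% false, and in MG1655 starvation 34.3%, 64.2% and 90.9%, with 3.82% false. For the pair of environmental strains it found 89.6%, 98.5% and 100%, with 5.88% false, and for differences in response 29.9%, 76.1% and 98.5%, with 5.56% false. DESeq2 made 11.6% false calls for differences in response and limma 46.6% in MG1655 starvation, so the latter is no check of that comparison. camera called the 1 changed list and 0 of 20 unchanged lists. Genes were simulated independently of each other, so this is no check of list calls where members are correlated. In the data the estimated correlation reached 0.594, for iron uptake in batch. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.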

Results

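RNA was sequenced from 4 Escherichia coli strains, each grown in glucose minimal medium at 37 °C under 3 conditions. MG1655 is the K-12 laboratory strain, IAI1 a commensal, TW11588 a soil isolate of clade IV and TW09308 a freshwater isolate of clade V. Chemostat cells were harvested at steady state on 0.5 g/l glucose. The dilution rate was 0.25, in a unit the labels do not give. Starvation cells came from steady-state chemostats 4 h after the medium flow was stopped, and batch cells from flasks with 1 g/l glucose. The labels conflict on the batch harvest, naming steady state in one place and flasks started from growing cells in another, so the growth phase of batch cells is not known. Each of the 12 groups had 2 libraries, which gave 24 libraries in all, 6 per strain and 8 per condition. The deposited values were raw read counts for 6291 genes of a pan-genome. This is a common gene set with one identifier (PAN) per gene and coordinates in each strain. The comparisons used the 3215 genes mapped in all 4 strains, of which 3198 had enough reads to be tested.

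The total counts of replicates 1 and 2 were as follows. MG1655 had 15340428 and 7947558 reads in chemostat, 11346140 and 16143697 in batch, and 605126 and 664474 in starvation. IAI1 had 5952221 and 5431163 in chemostat, 5830924 and 4161924 in batch, and 2468112 and 2004603 in starvation. TW11588 had 3519826 and 6214911 in chemostat, 6551668 and 7540526 in batch, and 5816446 and 4558725 in starvation. TW09308 had 11309105 and 8816184 in chemostat, 3227224 and 5073163 in batch, and 3468093 and 5528552 in starvation. Replicates correlated at r of 0.991 or more across genes in 11 of the 12 groups and at 0.968 in MG1655 starvation, the group with the fewest reads. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples. In a multidimensional scaling plot, libraries of one group lay together, and the first dimension (45.6% of variance) ran from batch through chemostat to starvation within each strain.

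**Figure D1:**
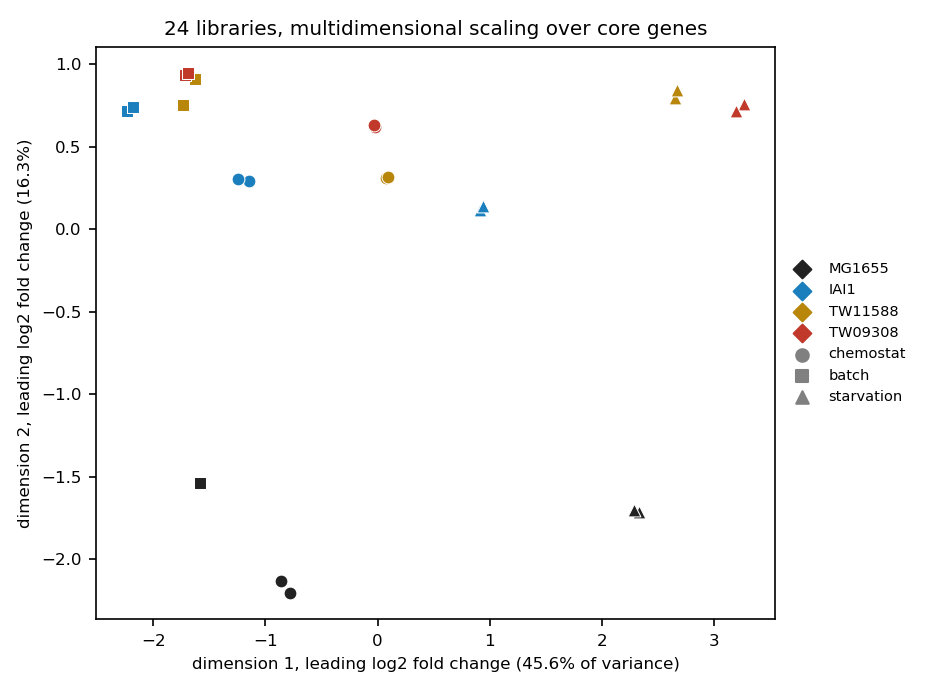
Multidimensional scaling of the 24 libraries over the core genes, with leading log2 fold change on both axes, colour for strain and shape for condition. Dimension 1 holds 45.6% of the variance and parts the conditions, dimension 2 holds 16.3% and parts MG1655 from the other strains.

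The first comparison asks which genes differ between chemostat cells and batch cells, whose growth phase at harvest is not settled by the labels. In batch, genes that take up scarce sugars or use acetate and fatty acids, and RpoS-dependent genes, were lower in the mean of the 4 strains, and pyrimidine genes were higher, also with an estimated correlation. Genes for ribosomes, translation factors, amino acids and purines were higher and those for alternative carbon sources lower with the preset correlation only (adjusted p = 0.189, 0.0972, 0.0643, 0.0643 and 0.0972 with an estimated correlation). Of 3198 genes, 2567 changed, 1234 upwards and 1333 downwards, and 939 passed in each strain by itself, 438 of them higher in all 4 and 441 lower in all 4. mglB (PAN002144, positions 2237372 to 2238370 on the complement strand of version 2 of the MG1655 sequence), the binding protein of the galactose and glucose transporter, fell from 3413 ± 639 to 172 ± 2.44 cpm (scaled counts from edgeR) in MG1655 (SD, n = 2). Its mean log2 fold change over the 4 strains was -4.53 ± 0.06 (SE), with an adjusted p of 7.53e-23 (edgeR quasi-likelihood test, Benjamini-Hochberg), and it was lower in all 4 strains.

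Genes for acetate and fatty acid use had the lowest list median, and all 13 measured members fell (median log2 -2.91, camera adjusted p = 3.96e-28, and adjusted p = 0.0174 with an estimated correlation). Among them were the acetate permease actP (PAN004199, 4281276 to 4282925, complement strand; -5.28 ± 0.06), the acetyl-CoA synthetase acs (PAN004201, 4283436 to 4285394, complement strand; -4.53 ± 0.07), the fatty acid oxidation gene fadB (-4.46) and the isocitrate lyase aceA (-2.91). In high-affinity sugar uptake, 20 of 21 genes fell and the galactose permease galP rose by 0.91 (median -2.86, adjusted p = 1.37e-29, and adjusted p = 0.0174 with an estimated correlation). Its strongest falls by p were those of mglB and of the maltose uptake genes lamB (-4.63), malK (-3.93) and malE (-3.35). The arabinose and xylose binding proteins araF (-4.45) and xylF (-4.22) fell as well. All 29 genes for alternative carbon sources fell (median -1.43, adjusted p = 9.55e-09, adjusted p = 0.0972 with an estimated correlation), among them tryptophanase tnaA (-4.21), the glycerol genes glpF (-3.67) and glpK (-2.77) and the dicarboxylate transporter dctA (-3.07). All 14 tested genes of the TCA cycle list fell (median -1.08, adjusted p = 3.17e-07, adjusted p = 0.0972 with an estimated correlation). So did 5 of 6 gluconeogenesis genes, led by pck at -3.17, with fbp at 0.05 (median -0.92, adjusted p = 0.00227, adjusted p = 0.143 with an estimated correlation). Outside these lists, glcD of glycolate oxidation (-4.15), lhgD of hydroxyglutarate oxidation (-3.71) and astC of arginine breakdown (-3.87) fell as well. Malate:quinone oxidoreductase (PAN002204) rose in all 4 strains, and without a symbol it was not in the TCA cycle list as tested.

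RpoS-dependent and acid resistance genes were lower in batch too, in the mean of the 4 strains. Of 22 genes that depend on RpoS, the sigma factor of general stress, 21 fell and the exonuclease gene xthA rose by 0.29 (median -1.66, adjusted p = 6.47e-12, and adjusted p = 0.0174 with an estimated correlation). aldB, an aldehyde dehydrogenase gene (PAN005302, 3752996 to 3754534, complement strand), fell by 5.02 ± 0.10 on the log2 scale (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.51e-20, lower in all 4 strains). csiD fell by 4.25 and dps, which protects DNA, fell by 2.58. The acid resistance list had 13 fixed members, of which 6 were matched to core genes. Among them hdeB, hdeA, hdeD and mdtF lie between positions 3653989 and 3661550 in MG1655. All 6 fell in the mean of the strains (median -1.83, adjusted p = 0.0049, adjusted p = 0.223 with an estimated correlation). Their strain medians were 0.35 in MG1655, 0.86 in IAI1, -4.41 in TW11588 and -5.06 in TW09308. The ribosome hibernation factors rmf (-3.41), raiA (-1.40) and hpf (-1.22), too few for a list test, all fell.

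Genes of growth and biosynthesis rose. All 53 ribosomal protein genes were higher, for example rplV (0.96) and rplC (0.93) (median 0.80, adjusted p = 5.73e-15, adjusted p = 0.189 with an estimated correlation). So were all 9 translation factors, infA by 1.32 (median 0.63, adjusted p = 0.00181, adjusted p = 0.0972 with an estimated correlation). In amino acid biosynthesis, 70 of 80 genes rose and leuA, ilvB, ilvN, cysE and gdhA fell (median 0.77, adjusted p = 5.41e-17, adjusted p = 0.0643 with an estimated correlation). argG of arginine synthesis (PAN003195, 3316659 to 3318002, forward strand) rose by 1.75 ± 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.73e-19, higher in all 4 strains), and the methionine synthase gene metE rose by 1.63. All 14 purine genes rose, among them purD (1.22) and guaB (1.31) (median 1.07, adjusted p = 2.67e-09, adjusted p = 0.0643 with an estimated correlation). All 10 pyrimidine genes rose too, among them carB (1.28) and pyrE (1.55) (median 0.85, adjusted p = 6.98e-05, and adjusted p = 0.0217 with an estimated correlation). Of 25 iron uptake genes 20 rose and fhuE fell (median 0.59, adjusted p = 0.0051, adjusted p = 0.61 with an estimated correlation), with fepA at 1.60. Other genes that rose were the RNA helicase rhlE (2.26), pdeI of cyclic-di-GMP breakdown (2.15), pppA (1.96), the NADH dehydrogenase ndh (1.86), the glutamate synthase genes gltD (1.82) and gltB (1.82), and the transporters dtpD (1.75) and lysP (1.70).

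The nitrogen and phosphate limitation lists were lower in batch with the preset correlation only. Nitrogen limitation had 13 genes that fell, such as astD (-3.53) and gltI (-1.66), and 4 that rose, glnK (2.88), glnL (1.43), glnG (1.07) and amtB (1.06) (median -1.12, adjusted p = 0.00102, adjusted p = 0.207 with an estimated correlation). Phosphate limitation had 14 genes that fell, led by ugpB (-3.09), and phoE at 0.09 (median -0.63, adjusted p = 0.00227, adjusted p = 0.0643 with an estimated correlation). The list test was not passed by flagella and chemotaxis (0 higher and 35 lower of 48, median -0.56, adjusted p = 0.315) or by glycolysis (11 higher and 5 lower of 17, 0.27, adjusted p = 0.0921). Nor did anaerobic metabolism pass, with 18 of 30 lower and nirB (1.08) and nirD (1.36) higher (median -0.30, adjusted p = 0.0536). Aerobic respiration had 13 higher and 13 lower of 30 (adjusted p = 0.362), heat shock 11 and 4 of 20 (0.15, adjusted p = 0.628) and oxidative stress 5 and 9 of 20 (adjusted p = 0.961). The SOS response had 4 and 6 of 15 (adjusted p = 0.87), and curli, cellulose and fimbriae 5 and 10 of 17 (-0.27, adjusted p = 0.825). The 5 higher genes of the last list were fimA, fimC, fimD, fimH and fimI of type 1 fimbriae, and the 5 higher oxidative stress genes ahpF, grxA, oxyR, zwf and gor. In heat shock the lower genes were clpA, clpB, degP and rpoH, in glycolysis pfkB, pykA, glk, ptsG and crr, and the higher SOS genes were recA, dinB, dinI and yebG. The median, mean and test differed in sign for respiration (median -0.02, mean 0.06, tested upwards), oxidative stress (median -0.09, tested upwards) and SOS (median 0.06, mean -0.05, tested upwards). In the colanic acid capsule none of 13 genes rose and 5 fell, rcsA (-0.92), wcaL (-0.55), wcaB, wcaJ (-0.64) and cpsG (-0.54), of which 2 passed adjusted over the list alone (list adjusted p = 0.879). The call of cpsG was lost without either library of TW11588 or TW09308 chemostat, or without IAI1 chemostat replicate 1 or TW11588 batch replicate 2 (-0.39 to -0.47). That of wcaJ was lost without either library of TW11588 or TW09308 chemostat, replicate 1 of MG1655 chemostat or TW11588 batch, or replicate 2 of IAI1 chemostat or of MG1655, IAI1 or TW09308 batch (-0.39 to -0.60). Adjusted over the list alone, 19 anaerobic and 14 heat shock genes passed, and every other list kept the count it had over all genes.

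Of the 24 lists tested in batch 15 passed and 4 did with an estimated correlation, namely acetate and fatty acid use, sugar uptake, RpoS and pyrimidines. Within single strains 1679 genes changed in MG1655 (765 higher), 1928 in IAI1 (973 higher), 2204 in TW11588 (1081 higher) and 2053 in TW09308 (1015 higher). With median-ratio size factors the median of all genes moved by 0.11 on the log2 scale, and the higher share of the calls moved from 48.1% to 55.4% in the mean of the strains, so changes of that size are relative to the scaling. The higher share was 45.6% in MG1655 and 56.1% with DESeq2, and 50.5% in IAI1 and 62.7% without either TW11588 chemostat library or either TW09308 chemostat library.

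**Figure D2:**
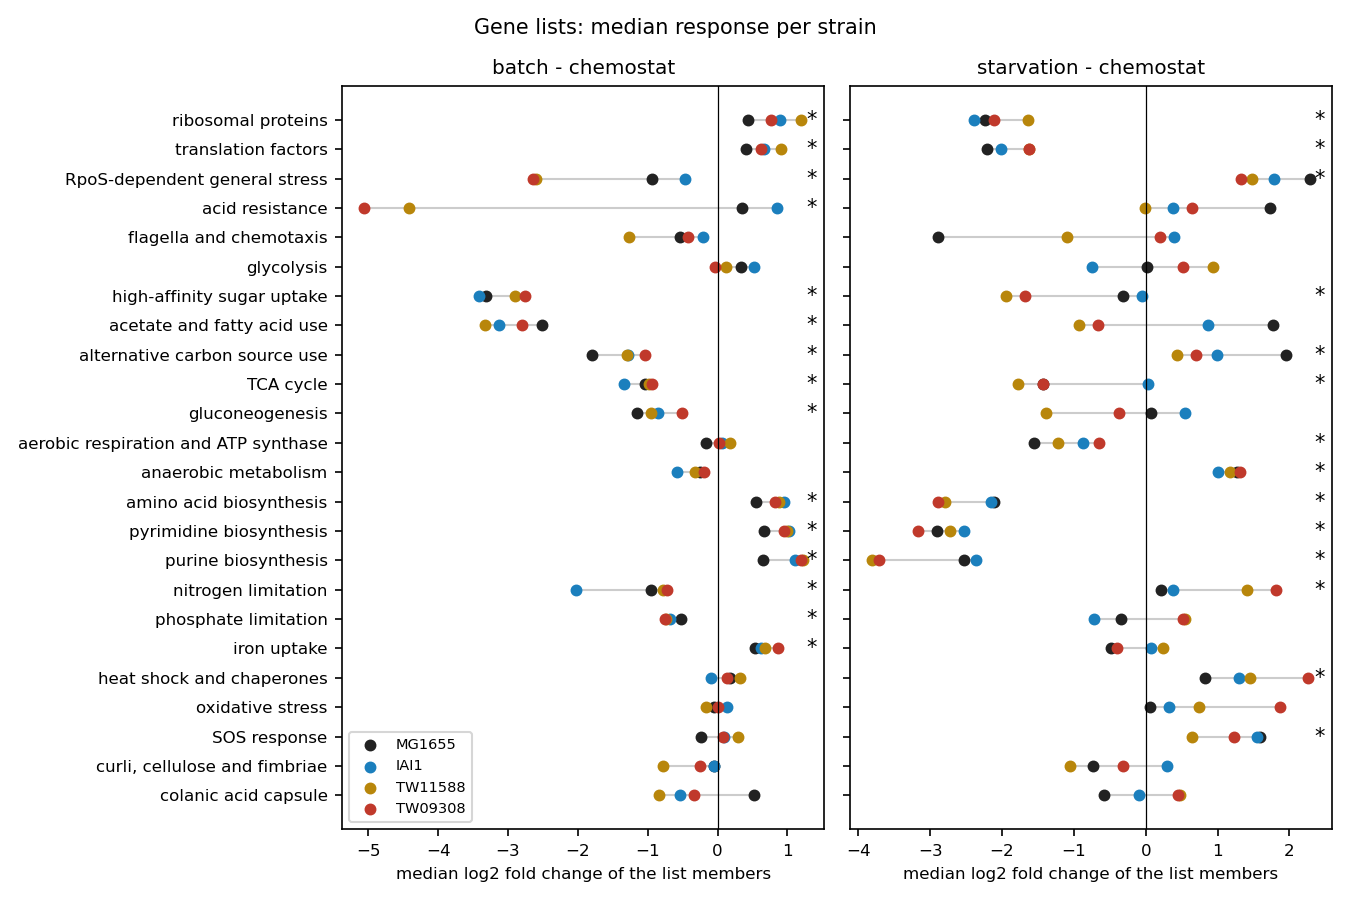
Median log2 fold change of the members of 24 gene lists in each strain, batch minus chemostat at the left and starvation minus chemostat at the right, with a point per strain and an asterisk where the list test of the 4-strain mean passed with the preset correlation. Batch medians of acid resistance run from -5.06 in TW09308 to 0.86 in IAI1, and ribosomal protein medians lie above 0 in batch and below 0 in starvation in all 4 strains.

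The second comparison asks which genes change when growing cells lose their glucose supply for 4 h. After starvation, genes for amino acid synthesis were lower in the mean of the 4 strains, also with an estimated correlation. With the preset correlation only, purine, pyrimidine, ribosomal and respiratory genes were lower (adjusted p = 0.0717, 0.0643, 0.0972 and 0.208 with an estimated correlation). RpoS-dependent, heat shock, SOS and anaerobic genes were higher, likewise only with the preset one (adjusted p = 0.0643, 0.222, 0.0831 and 0.261 with an estimated correlation). A total of 2687 genes changed, 1300 upwards and 1387 downwards, and 1504 passed in each strain by itself, 540 of them higher in all 4 and 658 lower in all 4. metE (PAN003935, 4011076 to 4013337, forward strand) stood at -5.22 ± 0.09 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.87e-23), from 8279 ± 1250 to 1104 ± 50.6 cpm in MG1655 and from 3402 ± 429 to 80.0 ± 10.4 in IAI1 (SD, n = 2). bssR, a regulator of biofilm formation (PAN000826, 877471 to 877854, forward strand), stood at 6.19 ± 0.18 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.16e-18), and was higher in all 4 strains.

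Amino acid biosynthesis was the one list that also passed with an estimated correlation. Of its 80 genes 78 fell, cysE rose by 0.38 and proA stood at -0.05 (median -2.45, adjusted p = 2.16e-26, and adjusted p = 0.0217 with an estimated correlation). ilvC (-4.34), cysJ (-4.32), cysD (-4.16), lysA (-3.94), thrA (-3.83) and glyA (-3.69) were among its falls. All 14 purine genes fell, such as purK (-4.78), purT (-4.29) and purM (-3.92) (median -3.06, adjusted p = 2.23e-10, adjusted p = 0.0717 with an estimated correlation). In pyrimidine synthesis 9 of 10 genes fell and the CTP synthase pyrG rose by 1.41 (median -2.94, adjusted p = 0.000578, adjusted p = 0.0643 with an estimated correlation), with carA (PAN000030, 29651 to 30799, forward strand) at -5.41 and carB at -4.38. The purine salvage gene apt (-3.81) and the iron transport gene efeO (-3.82) fell as well. The gene rsxA, which fell by its fitted value, was listed at 0 reads in both MG1655 starvation libraries and stood at -1.43, -2.93 and -3.06 in IAI1, TW11588 and TW09308.

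Of 53 ribosomal protein genes 49 fell and rplT (0.82), rpmE (0.72), rpmI (0.25) and rpsA (0.11) rose (median -2.07, adjusted p = 2.24e-21, adjusted p = 0.0972 with an estimated correlation). Of 9 translation factors 8 fell and the ribosome recycling factor frr rose by 1.19 (median -1.81, adjusted p = 0.000996, adjusted p = 0.0831 with an estimated correlation). Aerobic respiration and ATP synthase had 25 of 30 genes lower, such as atpE (-3.04) and atpA (-2.87), and cydB (0.47), ndh (0.26) and cydA (0.21) higher (median -1.10, adjusted p = 3.81e-07, adjusted p = 0.208 with an estimated correlation). In the TCA cycle 11 of 14 genes fell, among them sucC (-2.33) and sucD (-2.12), and acnA rose by 1.38 (median -1.17, adjusted p = 0.0156, adjusted p = 0.448 with an estimated correlation). Sugar uptake had 16 of 21 genes lower, led by malK (-5.73) and malE (-5.14), and araF (1.16), araG (1.78), araH (2.42) and xylH (1.05) higher (median -1.03, adjusted p = 0.00427, adjusted p = 0.323 with an estimated correlation).

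In the RpoS list 18 of 22 genes rose, katE (-1.88), osmE (-0.59) and xthA (-0.62) fell and narZ stood at 0.20 (median 1.57, adjusted p = 3.17e-07, adjusted p = 0.0643 with an estimated correlation). The universal stress gene uspB (PAN003514, 3637408 to 3637743, complement strand) rose by 5.11 ± 0.08, from 26.6 ± 2.90 to 3633 ± 162 cpm in MG1655 (SD, n = 2). The lipocalin blc rose by 4.29, dps by 3.52 and wrbA by 3.42. Heat shock and chaperone genes rose in 16 of 20 cases, such as dnaK (2.80), htpX (2.78) and clpX (2.55), while groL (-0.30), groS (-0.67) and degP (-0.20) fell (median 1.38, adjusted p = 4.25e-06, adjusted p = 0.222 with an estimated correlation). Of 15 SOS genes 11 rose, among them lexA (2.28) and sulA (2.15), and dinI fell by 0.81 (median 1.11, adjusted p = 0.00627, adjusted p = 0.0831 with an estimated correlation). Of 30 anaerobic genes 26 rose and none fell, for example frdD (2.66) and aspA (2.45) (median 1.01, adjusted p = 0.00145, adjusted p = 0.261 with an estimated correlation). The gene nirD had 0 reads in MG1655 starvation, where the floor of 3 reads lies above its chemostat level. Its 0 reads therefore do not settle a direction there. The list median was 1.11 with nirD set at that floor, a log2 value of 1.32 that is an upper bound and not a measured rise. Alternative carbon genes rose in 20 of 29 cases, such as glpD (3.88), dadA (3.42) and dadX (2.70), and tnaA (-2.48), glpK (-0.46), galK (-0.44), lldD (-0.32) and glpT (-0.23) fell (median 0.85, adjusted p = 0.00627, adjusted p = 0.333 with an estimated correlation). Nitrogen limitation had 10 of 17 genes higher, among them astC (4.59), astD (4.27) and astB (4.19) of arginine breakdown, and 6 lower (median 0.91, adjusted p = 0.0216, adjusted p = 0.333 with an estimated correlation). Its member glnK also had 0 reads in MG1655 starvation, with the floor above its chemostat level, and the list median stayed at 0.91 with glnK set at that floor. The serine deaminase sdaA (PAN001717, 1894956 to 1896320, forward strand) rose by 4.52 ± 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.91e-24). The transporters brnQ (4.41) and mntH (4.28) rose in all 4 strains.

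Among ribosome hibernation factors raiA rose by 4.32, rmf stood at -0.05 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.845) and hpf at 0.14 (adjusted p = 0.0327). The call of hpf was lost without either library of MG1655 chemostat, IAI1 chemostat, IAI1 starvation, TW09308 batch or TW09308 starvation, and without replicate 1 of MG1655 starvation, TW11588 chemostat, TW11588 starvation or TW09308 chemostat, at values from 0.035 to 0.134.

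Acid resistance did not pass the list test (hdeD, hdeB, hdeA and gadC higher and mdtF lower of 6, median 0.76, adjusted p = 0.589). Nor did flagella and chemotaxis (35 of 48 lower, fliR and tar higher, median -0.98, adjusted p = 0.362) or glycolysis (8 higher and 6 lower of 17, 0.08, adjusted p = 0.72). In glycolysis ptsG fell by 3.76. In acetate and fatty acid use 7 of 13 rose, led by fadD (3.26), and actP, aceA, acs, aceB and fadB fell (median 0.14, adjusted p = 0.6). Oxidative stress had 11 higher and 6 lower of 20 (median 0.47, adjusted p = 0.0997), with trxC at 4.18, and iron uptake had fepD, entF and tonB higher and 9 lower of 25 (median -0.10, adjusted p = 0.656). In gluconeogenesis fbp and glpX rose and pps, maeA and maeB fell (median -0.27, adjusted p = 0.745). Curli, cellulose and fimbriae had csgA, csgD, bcsC, bcsE and fimH higher and 7 lower of 17 (median -0.30, adjusted p = 0.745). Phosphate limitation had 6 higher, led by psiF (2.64), and phoA, pstB, pstS, ugpC and ugpE lower of 15, with a median of -0.03, a mean of 0.25 and an upward test (adjusted p = 0.6). In the colanic acid capsule wza (1.04) and wcaB (0.91) rose, rcsA fell by 1.67, and wcaG and gmd passed downwards by their fitted values, of 13 genes, with a median of 0.06, a mean of -0.25 and a downward test (adjusted p = 0.944). Both wcaG and gmd were listed at 0 reads in MG1655 starvation, where gmd was at least 1.38-fold lower than in chemostat against a floor of 3 reads. For wcaG that floor lies above the chemostat level, so its 0 reads show no fall in MG1655. The call of wcaB was lost without either library of MG1655 chemostat, TW09308 batch or TW09308 starvation, or without IAI1 starvation replicate 2 or replicate 1 of IAI1, TW11588 or TW09308 chemostat or of TW11588 starvation (0.555 to 0.906), and turned to -0.81 without MG1655 starvation replicate 1. Adjusted over the list alone, 13 acetate and fatty acid, 11 iron uptake and 3 colanic acid genes passed, and every other list kept its count. In all, 14 of 24 lists passed.

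Within single strains, starvation changed 2264 genes in MG1655 (1060 higher), 2400 in IAI1 (1265 higher), 2539 in TW11588 (1226 higher) and 2593 in TW09308 (1220 higher). The MG1655 starvation libraries were the shallowest, and in data simulated at these depths the test found 34.3% of 1.5-fold and 90.9% of 4-fold changes there.

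The third comparison asks whether strains respond differently to the same change of condition. In batch, the RpoS list had medians of -2.60 in TW11588 and -2.64 in TW09308 against -0.94 in MG1655 and -0.47 in IAI1. Acid resistance had medians of -4.41 and -5.06 in the first pair and of 0.35 and 0.86 in the second, so the medians differed in sign. No list test was run within a single strain, so a rise in the second pair was not tested. The responses of 2094 of 3198 genes differed between strains in batch and those of 2809 in starvation (edgeR quasi-likelihood F test). dps (PAN000802, 847631 to 848134, complement strand) had log2 changes in batch of -0.78 in MG1655, -1.11 in IAI1, -4.46 in TW11588 and -3.96 in TW09308 (Benjamini-Hochberg adjusted p = 9.96e-14 in edgeR). The glutamate antiporter gadC (PAN001452, 1566978 to 1568513, complement strand) stood at 570 ± 34.9 and 1613 ± 352 cpm in chemostat in TW11588 and TW09308, and at 13.7 ± 3.97 and 28.9 ± 3.61 in batch. In MG1655 it was at 33.6 ± 5.47 in chemostat and 37.2 ± 2.42 in batch, and in IAI1 at 19.8 ± 0.0121 and 14.1 ± 1.93 (SD, n = 2 throughout). The curli genes csgD, csgE, csgF and csgG were lowest in TW11588, with csgD (PAN001004, 1101769 to 1102419, complement strand) at -3.73 there against 0.93, -0.53 and -0.81 in MG1655, IAI1 and TW09308. The cyclic-di-GMP gene pdeR (-0.47, 0.61, -2.07 and -2.63 in MG1655, IAI1, TW11588 and TW09308) and the malate synthase glcB (-2.65, -4.77, -1.86 and -2.93) were also named for batch.

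Set against the mean of the other 3 strains, the batch response of the RpoS list was higher in MG1655 (18 of 22 genes, median 0.87, adjusted p = 1.01e-09) and IAI1 (20 genes, 1.74, 1.31e-12) and lower in TW11588 (17 genes, -1.08, 4.97e-12) and TW09308 (20 genes, -1.27, 2.30e-16). All 6 matched acid resistance genes, of 13 fixed, moved likewise, with medians of 3.59, 3.64, -3.33 and -4.08 in the same order (adjusted p of 1.32e-15, 1.94e-14, 1.07e-12 and 5.89e-21). Each strain also enters the mean that the others are set against, so the calls of a list depend on each other. These 8 calls also passed with an estimated correlation, with adjusted p from 0.0180 to 0.0264, as did 2 of the calls in starvation. Those were glycolysis in IAI1, lower in 15 of 17 genes (median -1.21, adjusted p = 1.86e-08, and adjusted p = 0.0264 with an estimated correlation), and glycolysis in TW11588, higher in 15 of 17 (median 0.82, adjusted p = 1.28e-07, and adjusted p = 0.0264 with an estimated correlation). In batch, 46 of 53 ribosomal protein genes rose less in MG1655 than in the mean of the others (median -0.56, adjusted p = 4.97e-12, adjusted p = 0.463 with an estimated correlation).

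In starvation, the lysine permease lysP (PAN002151, 2245085 to 2246554, complement strand) stood at -0.46 in MG1655, -2.61 in IAI1, 2.79 in TW11588 and 2.72 in TW09308 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.28e-16). The cystine binding gene tcyJ stood at 0.34, -0.87, 3.04 and 2.93. glcD (PAN002994, 3124544 to 3126043, complement strand) stood at 0.66, 1.73, -2.24 and -4.18 in that order of strains. glyA of serine and glycine metabolism stood at -2.95, -1.77, -4.51 and -5.50. The cellulose gene bcsC (1.66, -0.90, -1.35 and 2.01), the GTPase genes era (1.28, -1.84, 1.65 and 0.93) and obgE (2.89, 0.81, 3.73 and 5.09), and nadR of NAD metabolism (2.40, -1.07, 1.59 and 2.00) were also named. Against the mean of the others, 43 of 48 flagellar genes were lower in MG1655 (median -2.63, adjusted p = 7.47e-19, adjusted p = 0.0668 with an estimated correlation). There, 11 of 13 acetate and fatty acid genes were higher (median 2.20, adjusted p = 8.64e-12, adjusted p = 0.123 with an estimated correlation). In IAI1, 13 of 14 TCA cycle genes were higher (median 1.71, adjusted p = 1.11e-05, adjusted p = 0.319 with an estimated correlation). In TW09308, 16 of 20 heat shock genes were higher (median 0.91, adjusted p = 3.90e-05, adjusted p = 0.496 with an estimated correlation).

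Of 192 such tests of lists 76 passed, and 10 with an estimated correlation. The responses of pairs of strains, which share no library, correlated across the 3198 genes at a mean r of 0.718 in batch (rho 0.716), from 0.635 for IAI1 and TW09308 to 0.850 for TW11588 and TW09308, and at 0.672 in starvation (rho 0.673), from 0.613 to 0.824 for the same pairs. Genes are not independent replicates. In batch 279 genes, and in starvation 765, rose in one strain and fell in another.

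**Figure D3:**
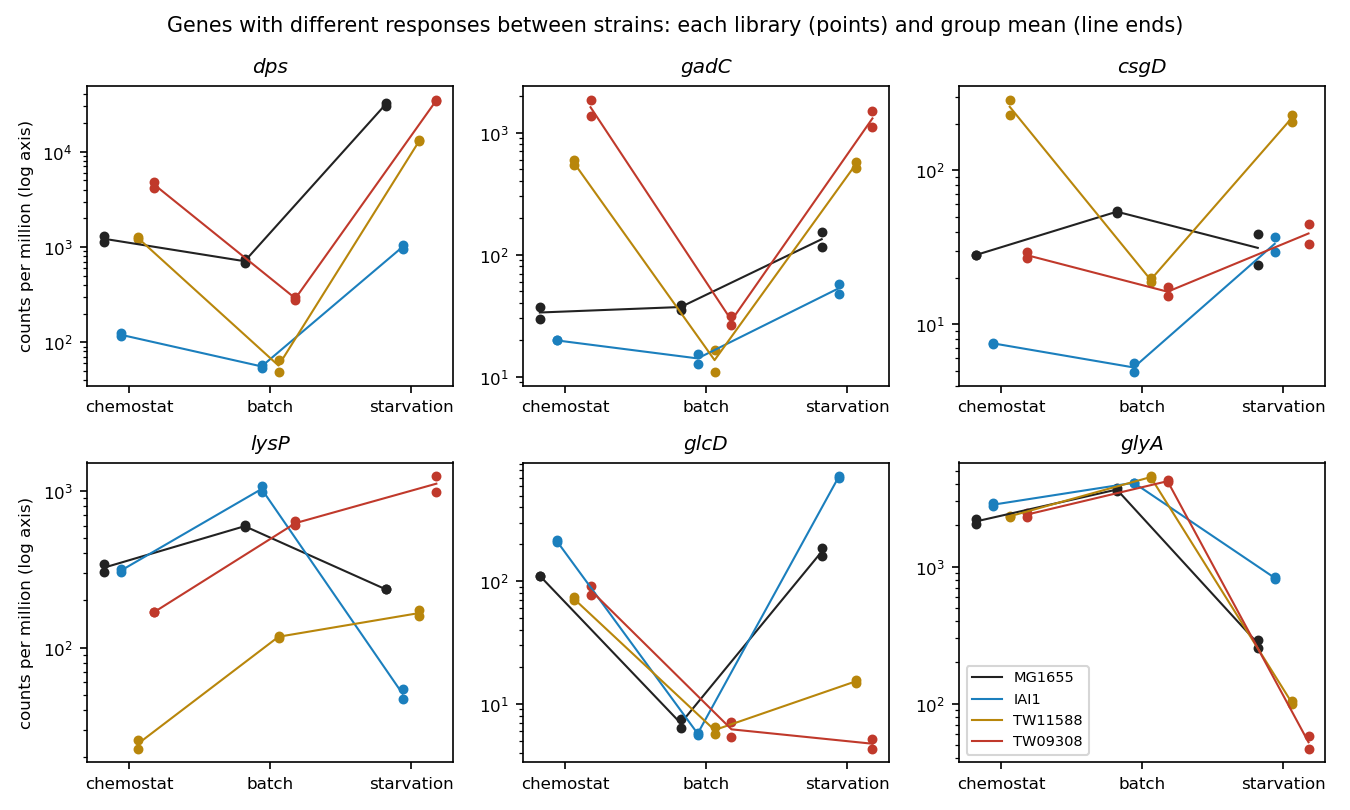
Scaled counts (cpm) on a log axis for 6 genes with different responses, with a point per library and lines joining the means of the 3 conditions within each strain. The mean of gadC went from 570 to 13.7 between chemostat and batch in TW11588 and from 1613 to 28.9 in TW09308, against 33.6 and 37.2 in MG1655.

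The fourth comparison asks how the strains differ in the chemostat, where medium and dilution rate were the same. MG1655 stood apart from the other 3 in motility genes, also with an estimated correlation. So did the soil and freshwater strains from the other pair in RpoS-dependent genes, in part because IAI1 was low in them. With the preset correlation only, the other 3 strains also differed from MG1655 in pyrimidine genes (adjusted p = 0.103 in each with an estimated correlation), and the soil and freshwater pair in acid resistance and curli, cellulose and fimbriae (adjusted p = 0.067 and 0.103 with an estimated correlation). By its list median, the curli, cellulose and fimbriae difference came mainly from TW11588. The core genes have their own coordinates in each strain. In all, 1973 genes differed between IAI1 and MG1655 (962 higher, 1011 lower). There were 2240 between TW11588 and MG1655 (1124 higher, 1116 lower) and 2284 between TW09308 and MG1655 (1157 higher, 1127 lower). All 48 genes of flagella and chemotaxis were lower in each of the 3 strains, with medians of -7.71 in IAI1 (camera adjusted p = 2.41e-145), -4.71 in TW11588 (1.15e-81) and -6.99 in TW09308 (2.89e-112). With an estimated correlation the adjusted p were 2.94e-05, 0.000636 and 0.000121. The aspartate receptor tar (PAN001787, 1969054 to 1970715, complement strand) stood at 4078 ± 276 cpm in MG1655, 2.17 ± 0.0445 in IAI1, from 13 and 11 reads, 9.72 ± 1.66 in TW11588 and 11.3 ± 1.82 in TW09308 (SD, n = 2). The chemotaxis gene cheY was lower by -7.69, -7.13 and -7.25, and the serine receptor tsr by -7.13, -6.35 and -6.65, in IAI1, TW11588 and TW09308.

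Genes for alternative carbon sources were lower in each of the 3 strains. In IAI1 20 of 29 were lower and dctA, garD, putA and putP higher (median -0.59, mean -1.75, adjusted p = 1.45e-05, adjusted p = 0.292 with an estimated correlation). In TW11588 17 were lower and lldD, lacZ and lacY higher (median -0.57, mean -2.19, adjusted p = 4.41e-07, adjusted p = 0.219 with an estimated correlation). In TW09308 21 were lower and dctA, lldD, srlA, srlE and putA higher (median -0.80, adjusted p = 5.16e-07, adjusted p = 0.219 with an estimated correlation). glpD (PAN003441, 3560036 to 3561541, forward strand) differed by -8.31, -7.27 and -6.32, and glpK (PAN004043, 4113737 to 4115245, complement strand) by -5.42, -6.11 and -5.41, in IAI1, TW11588 and TW09308. Pyrimidine genes were lower in IAI1 (7 of 10, pyrE higher, median -0.48, adjusted p = 0.00757), TW11588 (7, with pyrC, pyrE and pyrG higher, -0.66, adjusted p = 0.0058) and TW09308 (8, pyrE higher, -0.81, adjusted p = 0.00352), each with adjusted p = 0.103 with an estimated correlation. The aspartate carbamoyltransferase pyrB (PAN004388, 4469483 to 4470418, complement strand) stood at 1447 ± 23.2 cpm in MG1655 and at 39.8 ± 2.86, 38.9 ± 4.22 and 41.9 ± 6.97 in IAI1, TW11588 and TW09308 (SD, n = 2). The orotate phosphoribosyltransferase pyrE (PAN003664, 3813150 to 3813791, complement strand) was higher in each, by 2.55, 0.89 and 2.64.

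In IAI1, 20 of 22 RpoS genes were lower than in MG1655 and csiD higher at 1.22 (median -2.72, adjusted p = 1.32e-13, and adjusted p = 0.00605 with an estimated correlation), for example yhjG (-5.25), the trehalose gene otsB (-4.16) and dps (-3.35). TCA cycle genes were higher in 11 of 14 cases, led by sucB (1.73) (median 1.06, adjusted p = 0.000255, adjusted p = 0.329 with an estimated correlation). Nitrogen limitation genes were higher in 8 of 17, led by gltJ (2.88) and gltI (2.79), with glnG, glnL, amtB, astA and astC lower (median 0.37, adjusted p = 0.0231, adjusted p = 0.493 with an estimated correlation). Other genes higher in IAI1 were the outer membrane gene ompW (PAN001274, 1312044 to 1312682, forward strand; 3.42 ± 0.39), arnB (3.42 ± 0.19) and arnC (2.98) of lipid A modification, and hokC (3.27), whose counted region overlaps another gene in the IAI1 annotation.

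In TW11588, genes of curli, cellulose and fimbriae were higher in 13 of 17 cases, and fimA, fimC, fimD and fimI lower (median 3.19, adjusted p = 1.76e-10, and adjusted p = 0.0384 with an estimated correlation). The curli gene csgB (PAN001006, 1103174 to 1103629, forward strand) stood at 1148 ± 158 cpm against 8.22 ± 1.16 in MG1655 (SD, n = 2), a log2 difference of 7.10 ± 0.30 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.27e-15). The cellulose synthase gene bcsA (PAN003563, 3690641 to 3693259, complement strand) differed by 4.90. RpoS genes were higher in 15 of 22, with bolA and yhjG lower (median 1.26, adjusted p = 0.00133, adjusted p = 0.219 with an estimated correlation). All 6 matched acid resistance genes were higher (median 4.35, adjusted p = 2.59e-05, adjusted p = 0.19 with an estimated correlation). Nitrogen genes were higher in 11 of 17, with glnL, glnH, glnP and glnQ lower (median 1.00, adjusted p = 0.0219, adjusted p = 0.442 with an estimated correlation). Ribosomal protein genes were lower in 47 of 53, with rpsI, rplI and rpmH higher (median -0.51, adjusted p = 0.00187, adjusted p = 0.86 with an estimated correlation).

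In TW09308, 20 of 22 RpoS genes were higher and xthA and yhjG lower (median 1.43, adjusted p = 2.59e-05, adjusted p = 0.103 with an estimated correlation), led by the superoxide dismutase sodC at 4.76, csiD at 4.40 and aldB at 4.19. All 6 matched acid resistance genes were higher (median 4.91, adjusted p = 3.93e-06, adjusted p = 0.136 with an estimated correlation), led by hdeB (6.26) and gadC (5.57). Curli, cellulose and fimbriae had 10 of 17 genes higher and fimA, fimE and fimI lower (median 0.52, adjusted p = 0.0058, adjusted p = 0.308 with an estimated correlation), with bcsB at 4.86. Ribosomal proteins had 46 of 53 lower (median -0.70, adjusted p = 0.00133, adjusted p = 0.86 with an estimated correlation). The lipopolysaccharide gene waaH was higher by 4.84 and the glycerol phosphate dehydrogenase subunit glpB lower, at -8.99.

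TW11588 and TW09308 together differed from MG1655 and IAI1 in 2370 genes (1107 higher, 1263 lower), a comparison in which habitat and strain cannot be parted with a pair of strains on each side. RpoS genes were higher in 21 of 22 cases, with xthA at -0.50 (median 2.63, adjusted p = 1.28e-20, and adjusted p = 0.00118 with an estimated correlation), among them sodC (3.91), otsB (3.43) and wrbA (3.24). Part of that difference came from IAI1, whose median lay at -2.72 against MG1655, while those of TW11588 and TW09308 lay at 1.26 and 1.43 and did not pass with an estimated correlation (adjusted p = 0.219 and 0.103). All 6 matched acid resistance genes were higher (median 5.29, adjusted p = 1.58e-09, adjusted p = 0.067 with an estimated correlation), with hdeB at 6.52 and gadC at 5.21 ± 0.14 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.45e-18). Curli, cellulose and fimbriae had 12 of 17 higher and fimA, fimC, fimD and fimI lower (median 2.36, adjusted p = 1.43e-06, adjusted p = 0.103 with an estimated correlation), with bcsB at 3.85. By list medians that difference came mainly from TW11588, though the cellulose gene bcsB was also higher in TW09308 than in MG1655. Against MG1655 the list medians were 3.19 in TW11588, 0.52 in TW09308 and 0.78 in IAI1 (means 2.67, 1.02 and 0.45). Phosphate limitation had 12 of 15 higher, led by psiF (2.68), and phoU lower (median 0.75, adjusted p = 0.0279, adjusted p = 0.233 with an estimated correlation). Flagellar genes were lower in 45 of 48 cases (median -1.97, adjusted p = 4.46e-08, adjusted p = 0.233 with an estimated correlation). That difference came from MG1655, since IAI1 had the lowest flagellar median against MG1655 (-7.71, with -4.71 and -6.99 in TW11588 and TW09308). Also lower were alternative carbon (21 of 29, with lldD, lacY, srlA and srlE higher, -0.67, adjusted p = 3.89e-05, adjusted p = 0.301 with an estimated correlation) and ribosomal proteins (47 of 53, rpmH higher, -0.56, adjusted p = 3.89e-05, adjusted p = 0.762 with an estimated correlation). The last were pyrimidines (7 of 10, with pyrC, pyrE and pyrG higher, -0.47, adjusted p = 0.0416, adjusted p = 0.219 with an estimated correlation) and respiration (22 of 30, -0.39, adjusted p = 0.0416, adjusted p = 0.86 with an estimated correlation). Against MG1655, alternative carbon means were -1.75 in IAI1, -2.19 in TW11588 and -2.24 in TW09308. Pyrimidine means were -1.09, -1.20 and -1.23 in that order. Much of both differences therefore came from MG1655. The alcohol dehydrogenase adhP was higher by 4.76 ± 0.10 and the zinc response regulator zraR lower, at -3.88 ± 0.17.

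Of 96 list tests between strains 30 passed, 6 with an estimated correlation. Adjusted over the list alone, the counts given for the passing lists were the same except for 5 nitrogen genes lower in TW11588, 47 ribosomal protein genes lower and 2 pyrimidine genes higher in TW09308, and 48 ribosomal protein genes lower in the environmental pair. List members named as exceptions to the direction of their list were chosen after their values were seen.

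**Figure D4:**
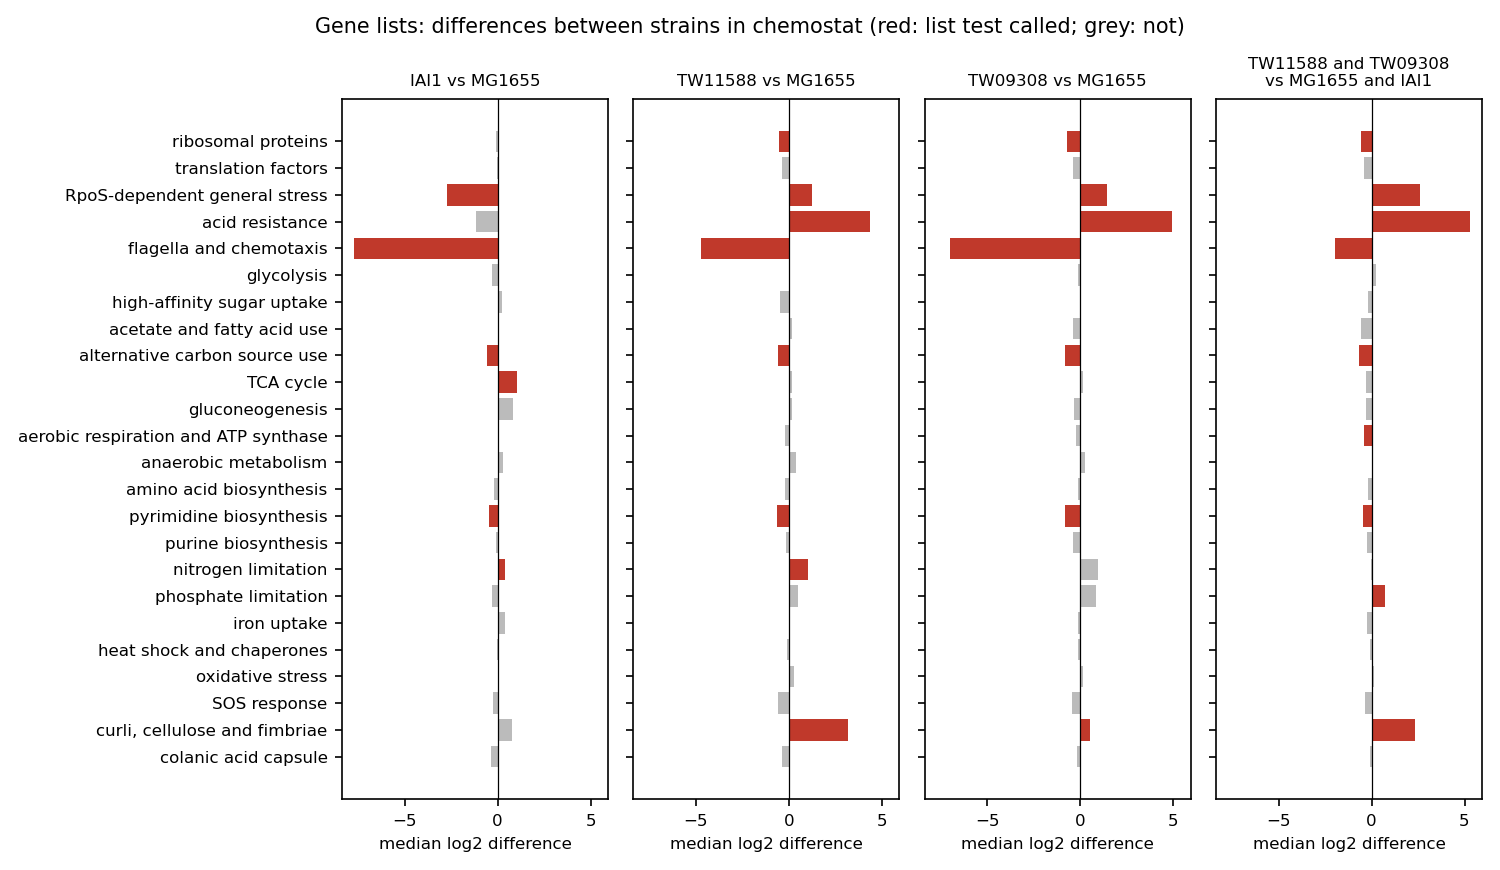
Median log2 difference of the members of 24 gene lists in the chemostat for IAI1, TW11588 and TW09308 against MG1655 and for TW11588 and TW09308 together against MG1655 and IAI1, with red bars where the list test passed with the preset correlation and grey bars elsewhere. The flagellar medians are -7.71, -4.71, -6.99 and -1.97 from left to right.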

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

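Chosen after the results were seen were the tests of sequence divergence, the test of a few abundant genes, the test of list medians at equal depth, the test of lists called without each MG1655 starvation library in turn, and thinning all libraries to the smallest, while the other tests were written down before their values were computed.

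Responses differed between strains for 2094 genes in batch and 2809 in starvation. In batch the adjusted p (edgeR quasi-likelihood F test, Benjamini-Hochberg) of the 8 genes named were those of dps (9.962e-14), gadC (1.989e-13), csgD (5.591e-13), csgG (6.412e-13), csgE (1.777e-12), pdeR (2.821e-12), glcB (3.053e-12) and csgF (3.571e-12). In starvation they were those of lysP (5.284e-16), glcD (1.289e-15), tcyJ (1.781e-15), era (2.770e-15), glyA (5.445e-15), bcsC (7.434e-15), obgE (7.434e-15) and nadR (7.896e-15). Lists whose batch response differed from the mean of the other 3 strains numbered 13 in MG1655, 8 in IAI1, 8 in TW11588 and 7 in TW09308. With an estimated correlation 2 passed in each strain. In starvation they numbered 11, 7, 13 and 9, and with an estimated correlation 0, 1, 1 and 0.

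Genes not shared by the 4 strains took 9.45 ± 1.38% of reads in MG1655, 10.03 ± 1.32% in IAI1, 7.11 ± 0.664% in TW11588 and 10.7 ± 1.07% in TW09308 (SD, n = 6 libraries). They entered only the fits of single strains.

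RpoS-dependent and acid resistance genes were higher in TW11588 and TW09308 than in MG1655 and IAI1 in chemostat, the acid list only with the preset correlation (adjusted p = 0.067 with an estimated correlation). Part of the RpoS difference came from IAI1, at a median of -2.72 against MG1655 (adjusted p = 0.00605 with an estimated correlation), while TW11588 and TW09308 stood at 1.26 and 1.43 and did not pass so (0.219 and 0.103). Gene length differences between strains could raise counts, but the 16 of 28 members with equal length in all strains had a median difference of 2.81 (quartiles 2.10 to 3.41), which excludes length as the cause; reads lost or gained through sequence divergence would act alike in every condition, but the difference in chemostat exceeded that in batch by a median of 1.91 (quartiles 1.44 to 2.96), which excludes divergence as the main cause. A few genes taking most of the counts is excluded, since the 10 most abundant genes held at most 15.8% of reads in MG1655 or IAI1, which can lower all others by at most 0.25 on the log2 scale, against a median difference of 2.82 (lower quartile 2.10). Whether RpoS activity in slow growth is higher in these strains or lower in IAI1 might be tested by the same chemostats with rpoS deleted.

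Flagellar, glycerol and pyrimidine genes were higher in MG1655 than in the other strains in chemostat, the alternative carbon and pyrimidine lists only with the preset correlation (adjusted p from 0.103 to 0.292 with an estimated correlation). Reads lost in the other strains through sequence divergence cannot be told apart from a real difference in the flagellar part, since the difference in chemostat was close to that in batch (median -0.01, quartiles -0.38 to 0.35), and though that in starvation was lower by 2.63 (quartiles 1.96 to 3.38) it remained at 3.85, with medians of 7 to 21.5 reads per gene in the other strains there. Loss of repression of the glycerol-3-phosphate genes in MG1655 may account for the glycerol part, as the 7 glp members had a median of -6.69 in the other strains and the 22 other members one of -0.34. Low expression of pyrE in MG1655 cannot be told apart from other causes of the pyrimidine part, since pyrE differed by at least 0.89 but not by 2-fold in every strain. Sequencing glpR and the rph-pyrE region of this MG1655 stock, and adding uracil to its chemostat, would test both.

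Responses to starvation specific to MG1655 rest on the shallowest libraries. With all libraries thinned to the smallest, 10 of 11 lists kept the sign and at least 0.5 of the size of their median. Unequal depth therefore did not make the size of most list medians. Of the 1609 genes called before, 1145 passed again with the same sign, of 1196 called then. Thinning to 605126 reads leaves the MG1655 starvation libraries (605126 and 664474 reads) nearly as they were. It cannot show whether noise from their own low depth made these values. By calls, 7 of 11 lists kept theirs. Alternative carbon (median 0.75, quartiles -0.36 to 1.51, before, and 0.69, -0.22 to 1.36, after), respiration (-0.46, -0.74 to -0.08, and -0.40, -0.67 to -0.03), nitrogen (0.93, -0.53 to 2.70, and 0.89, -0.31 to 2.68) and oxidative stress (-0.51, -0.91 to 0.50, and -0.14, -0.998 to 0.58) did not. Thinning lowers power in the deeper libraries, so for these 4 unequal depth cannot be told apart from a real difference. A deviating MG1655 starvation library did not make most of the calls, since 9 of 11 lists passed without replicate 1 and 9 without replicate 2, but only 7 passed both times; respiration (median -0.38, quartiles -0.65 to -0.07, after) and iron uptake (-0.60, -1.36 to -0.11, before, and -0.34, -1.23 to 0.13, after) lost theirs without replicate 1, amino acid biosynthesis (0.57, 0.00 to 1.25, and 0.54, -0.04 to 1.27) and oxidative stress (-0.52, -1.02 to 0.50, after) without replicate 2, and with a lone library left for these 4 a deviating library cannot be told apart from a real difference. Sequencing these libraries to the depth of the others would test low depth, and further MG1655 starvation libraries would test a deviating library.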

How the results depend on the processing

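Values move with these choices, and the cause of each move was not tested except where it follows by construction. Each group has 2 libraries, so in leave-one-out the lone library is assumed to vary like the other groups. The MG1655 starvation libraries have 605126 and 664474 reads, which limits what can be found there. limma on the deposited signal values made 46.6% false calls in simulated MG1655 starvation, so it is no check there, and DESeq2 11.6% for differences in response. Keeping rRNA and tRNA was not run, as 0 genes are named as such. Of 691 named results 656 kept their call in every setting in which they were tested, the 2-fold minimum aside, and 35 did not. Of the added settings, leaving out the MG1655 starvation group was not run for named genes. With the stricter filter 617 kept their call and 1 did not, and genes it removed were not tested.

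A 2-fold minimum left by construction fewer genes, 626 in batch in the mean of 4 strains, 404 in MG1655, 750 in IAI1, 935 in TW11588 and 763 in TW09308. In starvation it left 1568 in the mean, 1453 in IAI1 and 1673 in TW11588, and between strains 660, 928 and 838 for IAI1, TW11588 and TW09308 against MG1655 and 786 for the environmental pair.

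Thinning, added later, left 836 genes in MG1655 batch and 1195 in IAI1 batch, 1110, 1459 and 1427 for IAI1, TW11588 and TW09308 against MG1655, and 1046 with different batch responses. It turned the direction of the curli, cellulose and fimbriae list in MG1655 batch (adjusted p = 0.943), and lowered the agreement of strains in batch to 0.615. hpf in starvation went to 0.006 and wcaL in batch to -0.33.

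Agreement in batch was 0.752 with the stricter filter. In starvation it was 0.732 with it, 0.697 with DESeq2 and 0.694 with limma. With an estimated correlation 5 response lists, 10 strain-specific lists and 6 strain lists passed, and with fry 46, 127 and 73. With a replicate block 29, 71 and 30 passed. The within-strain block called 2526 genes in batch and 2662 in starvation, and 2593 and 2688 with the TW09308 chemostat numbers crossed, where the numbers had correlated at -0.39 and -0.30.

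Median-ratio factors moved the median of all genes in TW09308 starvation by 0.164. With the stricter filter the share of higher calls in batch was 57.1% in the mean, 61.2% in MG1655 and 61.8% in IAI1. The length offset took rplL in TW11588 to -0.30, where it no longer passed.

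With each of the 24 libraries left out in turn, the counts ran as follows. Batch gave 2496 to 2591 in the mean, 1255 to 1803 in MG1655, 1607 to 2059 in IAI1, 2007 to 2310 in TW11588 and 1788 to 2078 in TW09308. Starvation gave 2587 to 2690, 2021 to 2278, 2192 to 2413, 2398 to 2543 and 2441 to 2640 in that order. Strain differences gave 1656 to 2035, 1901 to 2279, 2040 to 2293 and, for the environmental pair, 2241 to 2391. Different responses gave 1922 to 2246 in batch and 2741 to 2815 in starvation, and agreement 0.707 to 0.718 and 0.642 to 0.674. wcaB in starvation ran from -0.813 without MG1655 starvation replicate 1 to 1.18 without replicate 2.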

Other observations

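The genes in the first and second paragraphs were chosen after their values were seen, and the splits in the last were planned before.

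Genes outside the core were fitted within each strain alone. In batch 352 of 922 changed in MG1655, 468 of 915 in IAI1, 457 of 836 in TW11588 and 469 of 1159 in TW09308, and in starvation 460, 591, 583 and 789. The share that changed in batch was below that of core genes in each strain, at 38.2% against 54.0% in MG1655, 51.1% against 63.0% in IAI1, 54.7% against 73.7% in TW11588 and 40.5% against 58.8% in TW09308. Genes outside the core had fewer reads each, with 1067 mapped genes taking 9.45% of reads in MG1655. The shares were not compared at equal reads per gene, so lower power cannot be told apart from a weaker response. The variant ribosomal protein L31 type B (PAN000351) was higher in batch by 2.14 in MG1655, 3.35 in IAI1 and 3.64 in TW09308. Glutamate decarboxylase A (PAN003546) fell by 6.60 in batch in TW09308 and glutamate decarboxylase B (PAN001453) fell by 5.51 in TW11588, where they joined the fall of gadC. A further entry with the product text of glutamate decarboxylase B (PAN006407) stood at -5.33 in TW11588 and -5.92 in TW09308. Whether these entries share reads was not checked, so they are not separate results for A and B. In IAI1 an oxidoreductase for L-1,2-propanediol (PAN002724) fell by 5.38 and L-fuculose phosphate aldolase (PAN002725) fell by 5.03. In starvation a capsule sugar phosphate isomerase (PAN002957) fell by 5.70 in TW09308 and by 5.21 in TW11588, and a phage Gam inhibitor (PAN001112) rose by 6.16 in TW09308.

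Some of the largest changes of core genes fell on genes without a symbol here. In batch, malate:quinone oxidoreductase (PAN002204) rose by 3.34 ± 0.07 and a glutamate and aspartate symporter (PAN004210) by 3.10, each in all 4 strains. In starvation, an inner membrane protein (PAN001223) rose by 6.33 ± 0.08, a SpoVR family protein (PAN001201) by 5.62 and a PrkA family kinase (PAN001691) by 4.52, each in all 4 strains.

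Other groupings of the samples were tried. For the mean of 4 strains in batch the real split called 2567 genes and the highest of the other splits 2268, and 1 of 100 splits called as many. In starvation the real split called 2687, the highest of the others 2511, and 1 of 100 called as many. Splits that mix conditions within a group raise its spread, so the real split was likely to call the most. Neither result excludes chance differences between cultures. For the environmental pair, with strains pooled within a side, the real split called 1645 and the highest of the others 763, and 1 of 35 called as many. Only 3 of those 35 splits keep strains whole, so chance in how strains were paired is not excluded.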
